A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

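RNA from exponentially growing S. cerevisiae cultures was reverse-transcribed, labelled with biotin by in vitro transcription and hybridised to Affymetrix yeast arrays, per the labels' protocols. The labels give 3 arrays of the wild-type strain FY4 and 2 arrays of a PHO2 deletion strain, and the groups and replicate numbers were taken from the sample titles. The deposited values are a probe set intensity on a linear scale, 1 value per probe set and array. The submitters' processing notes name R 2.8.0, the affy package and RMA, a method of background correction, quantile normalization and median polish that gives log2 values. The deposited values run from 9.49 to 37719, so they are linear signals rather than log2 values. That RMA output was turned back to the linear scale is an inference from these values. The design had assumed log2 values, and log2 of the deposited signal was taken before every test. Which arrays were normalized together, and the array's library file, are not given in the sources used here. No column of another sample was used (0 such columns).

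The table holds 10928 probe sets. The platform annotation names genes for part of them and 3683 are unnamed here, 213 of which are control or reporter probe sets by their identifiers. A single S. cerevisiae gene was matched for 5498 probe sets, through the gene number or locus tag in the gene table of assembly R64, which updated 12 symbols. The 1747 other annotated probe sets were not matched in that table, 1 with several genes among them. The array also carries probe sets for fission yeast, and these unmatched probe sets served as the background. For 47 genes with more than 1 probe set the one with the highest mean over all 5 arrays was used, which left 5449 genes. No genome build is named for the deposited values, so no coordinates are given, and assembly R64 was used for names, coding length and neighbours. The background bound was the 95th percentile of the log2 values of the unmatched probe sets, 6.44 (signal 86.9), and 130 genes had a mean below it. No dim gene was left out of the tests. Values near the bound understate true fold changes, and a fold against a group below it is given as at least the fold above the bound. Quantile normalization forces similar distributions on the arrays, so a change common to most transcripts would not be seen.

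Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, arrays labelled PHO2 deletion minus wild-type, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 3 residual and 2.23 prior degrees of freedom. Errors of differences are limma's moderated standard errors, and SDs are over 3 and 2 arrays. Differences and values of genes are on the log2 scale unless a fold or percentage is named. A gene is said to rise, fall or change only where it passed the threshold. Probe sets without annotation were tested in a fit of their own. With groups of 3 and 2, a permutation of the arrays allows 10 splits and cannot pass the threshold.

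Fixed before the data were examined were 27 gene lists, the test, the rule for named genes and most alternatives. The lists cover purine synthesis, histidine synthesis, one-carbon metabolism with glycine and serine, GMP synthesis with purine salvage and PRPP, phosphate-responsive genes, phosphate signalling, other amino acids, sulfur and methionine, pyrimidines, cytosolic ribosomal proteins, ribosome biogenesis, general stress, glycolysis and fermentation, hexose transport, the tricarboxylic acid cycle and respiratory chain, gluconeogenesis, iron, zinc, histones, nitrogen use, phospholipids, thiamine and pyridoxine, a-cell markers, alpha-cell markers, haploid genes and sporulation. The first 5 are the main lists. A further list was tested with them and is not reported here. List members without a matched probe set were not analysed here, the ADE5,7 gene of purine synthesis and PHO12 among them. List shifts were tested with camera in limma (inter-gene correlation 0.01, adjusted over the 27 lists), with camera on an estimated correlation and camera on ranks as alternatives. The fry test, which sets a list against no change rather than against other genes, was run as a separate question. All 10 list calls of camera were lost with the estimated correlation, where camera tests on the 3 residual degrees of freedom of the fit. Lists with an estimated correlation below 0 lost their calls too. The unadjusted camera p went from 7.1e-08 to 0.010 for the one-carbon list (correlation -0.06). For the a-cell list (-0.09) it went from 4.8e-04 to 0.037. The loss is therefore no measure of correlation between genes alone. On ranks, with the preset correlation, camera gave the same calls for all 27 lists. Counts adjusted over a list alone are to be read against the 29.4% of all genes with an unadjusted p below 0.05 by limma. In the purine, histidine, one-carbon, stress and respiratory lists that adjustment removed none of the members with an unadjusted p below 0.05 (9, 5, 13, 23 and 35).

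Named genes are PHO2 and its neighbours, the 10 largest rises and 10 largest falls among genes past the threshold with both arrays labelled PHO2 deletion beyond all 3 wild-type arrays, and up to 4 members with the smallest p of each list with a called member or a called shift and of each main list. Other members are named where a list is described, and PHO5, PHO84, HO, FCY2, GUA1, FCY22 and PAU21 were chosen after their values were seen. Named genes on probe sets marked as shared between sequences are IMD2, HXT17, HXT7, HXT13, HHF1, THI13 and SNZ3. Alternatives changed 1 choice at a time: a second quantile normalization, subtraction of array medians, eBayes with a trend or robust, filters on dim genes, the mean of a gene's probe sets, all probe sets in the test, array weights, the replicate number as a block, other thresholds and each array left out. A correction for coding length (lowess of each array's deviations on log2 length, span 0.3) and a filter of genes of 600 nt or less were added after the data were seen. Leaving out 1 array labelled PHO2 deletion leaves a lone array that is assumed to vary like the wild-type arrays.

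The procedure was tested on simulated data of the same 5449 genes with 200 genes changed. It recovered 54.5% of changes of 0.5 log2 units, 89.6% of changes of 1 and 92.5% of changes of 2, and 5 of 167 calls (2.99%) were false. The 1 shifted gene list was the 1 called. Simulated genes varied independently of each other, without a length trend or differences between whole arrays. Their variances were drawn from the prior that limma fitted, with normal noise, as the test itself assumes. The low share of false calls was therefore largely set in advance. In the real data the estimated correlation was 0.59 for the stress list and 0.70 for ribosome biogenesis. The simulation therefore cannot say how often list calls or gene calls are false where genes vary together. Figures were drawn with matplotlib 3.10.9.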

Results

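Transcript levels of budding yeast (Saccharomyces cerevisiae) were measured on 5 Affymetrix expression arrays. Of these, 3 carried RNA of the prototrophic reference strain FY4 (wild-type) and 2 carried RNA of a strain labelled as a deletion of PHO2. PHO2, also called BAS2, encodes a homeodomain transcription factor known to act with Bas1 at genes of purine and histidine synthesis, with Pho4 at phosphate-responsive genes and with Swi5 at HO. Per the labels, cultures grew exponentially at one cell density in glucose minimal medium. The comparison asks which transcripts differ between the deletion strain and the reference strain. The median signal over all 10928 probe sets, those without a matched gene included, was 260, 253 and 244 on the wild-type arrays. It was 313 and 297 on the arrays labelled PHO2 deletion. Over the 5449 genes alone the median log2 values were closer, at 11.13, 11.16 and 11.09 against 11.18 and 11.16. Between 97.3% and 97.9% of the 5449 S. cerevisiae genes lay above the background bound on each array. Gene values correlated across genes with r between 0.988 and 0.995 within the wild-type group and with r = 0.994 between the arrays labelled PHO2 deletion. No pair of arrays shared an identical value (0 of them). The number of arrays limits the precision of every value below, and nothing in the labels says that replicates came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

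The signal of the PHO2 probe set did not separate the groups. PHO2 (YDL106C) had log2 values of 10.72, 10.54 and 10.38 on the wild-type arrays, a mean of 10.55 ± 0.17 (SD, n = 3). The arrays labelled PHO2 deletion gave 10.07 and 10.84, a mean of 10.46 ± 0.55 (SD, n = 2). The difference was -0.09 (SE 0.24, adjusted p = 0.825 by limma), smaller than the spread between replicates, and every value lay far above the background bound of 6.44. The extent of the deletion and the position of the probes are not given in the sources used here, and a probe outside the deleted part would check nothing. The group names are therefore used as labels throughout, and each direction below is that of the arrays so labelled. The neighbours of PHO2 on the chromosome, MSS2 (log2 difference -0.29, adjusted p = 0.109) and NSE4 (0.21), did not pass the test. A different mark did separate the groups. Of 47 reporter probe sets, which stand for foreign sequences used in yeast constructs, 1 gave log2 values of 4.38, 4.58 and 4.29 on the wild-type arrays, below the background bound. It gave 14.35 and 14.38 on the arrays labelled PHO2 deletion, whose mean was at least 243-fold higher than that of wild-type, taken at the bound (adjusted p = 3.4e-07 by limma over the probe sets without annotation). Which sequence it represents is not given in the sources used here.

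**Figure D1:**
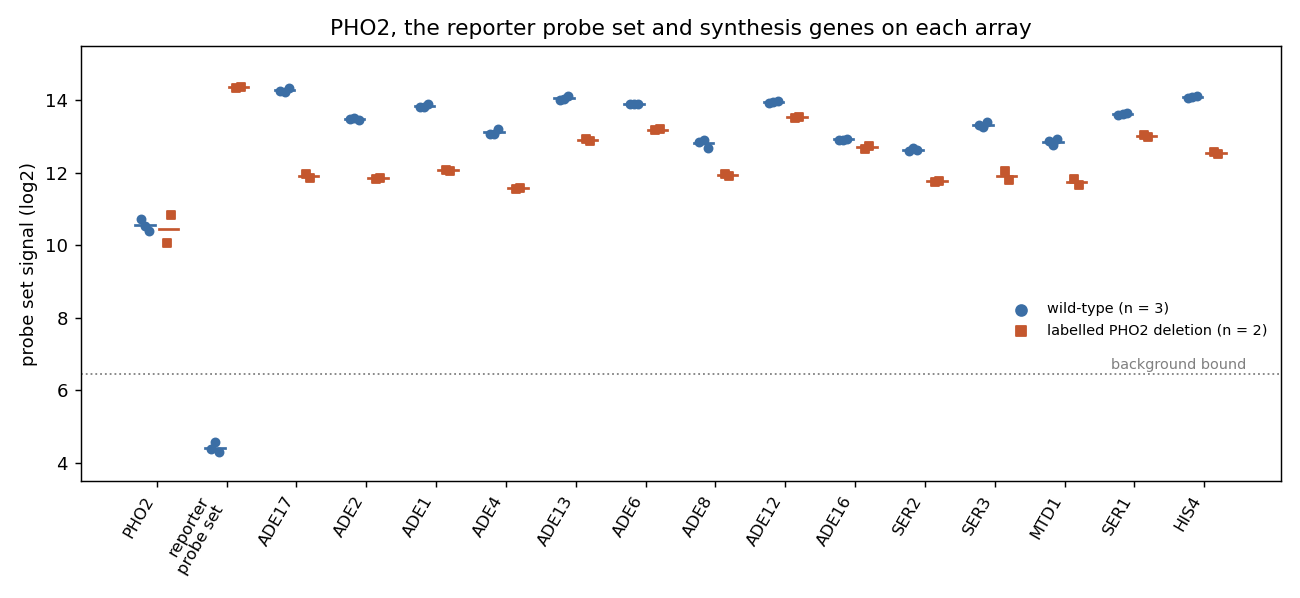
Probe set signal on each array (y axis, log2) for PHO2, the bright reporter probe set, the 9 measured purine synthesis genes, 4 one-carbon and serine genes and HIS4 (x axis); circles are the 3 wild-type arrays, squares the 2 arrays labelled PHO2 deletion, short lines group means and the dotted line the background bound. PHO2 overlaps between the groups, the reporter probe set lies near 4.42 against 14.36, and every purine gene is lower on both arrays labelled PHO2 deletion than on all wild-type arrays.

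Between the groups, 275 genes changed, of which 173 rose and 102 fell in the arrays labelled PHO2 deletion (limma, adjusted p below 0.05), and 55 of them by at least 1 log2 unit (44 up, 11 down). YRO2, a membrane protein related to the heat shock protein Hsp30, rose most, from 8.99 ± 0.06 (SD, n = 3) to 12.55 ± 0.18 (SD, n = 2), an 11.8-fold increase (log2 3.56, SE 0.09, adjusted p = 4.2e-04). FCY21, a purine-cytosine permease family member, rose 8.10-fold (log2 3.02, SE 0.10, adjusted p = 4.2e-04). YGP1, a secreted cell wall glycoprotein, rose 7.71-fold (log2 2.95, SE 0.12, adjusted p = 8.6e-04). The next in size were the small uncharacterised gene YER053C-A (log2 2.59), RTC3 (2.26), the permease gene SEO1 (1.78), the small heat shock protein gene HSP12 (1.69), FMP16 (1.63), the cell wall mannoprotein gene HPF1 (1.61) and GPG1 (1.56). The 10 largest falls were led by ADE17, to 19.4% of the wild-type level, and held 5 genes of purine synthesis (ADE17, ADE1, ADE2, ADE4 and ADE13), described below with HIS4, SER3 and HPT1. CEM1, the mitochondrial beta-keto-acyl synthase, fell by 1.32 (SE 0.07, adjusted p = 0.0020). YDL159W-A is among the 10 by the fit, but its mean lay below the background bound in both groups (5.91 and 4.51), so no size is given. The count of called genes depended on single arrays: it was 23 without wild-type replicate 1. It was 257 (49 fallen) without wild-type replicate 2 and 243 (55 fallen) without wild-type replicate 3. The count also dropped strongly without either array labelled PHO2 deletion, which leaves a lone array in that group. YRO2, FCY21, YGP1, SEO1 and CEM1 passed the test without any 1 array, YER053C-A, RTC3, HSP12, FMP16 and GPG1 did not without wild-type replicate 1 or either array labelled PHO2 deletion (adjusted p from 0.0733 to 0.207), and HPF1 did not without either array labelled PHO2 deletion (0.0723 and 0.0535).

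Purine synthesis was the most strongly lowered pathway. Of its 9 measured genes, 8 fell in the arrays labelled PHO2 deletion, and all 9 fell when adjusted over the list alone. The list median was -1.15, or 45.1% of the wild-type level. ADE17, which carries out the last steps to IMP, fell by 2.37 (SE 0.07, adjusted p = 4.2e-04), from 14.28 ± 0.06 (SD, n = 3) to 11.91 ± 0.08 (SD, n = 2). ADE1 (-1.78, SE 0.06), ADE2 (-1.63, SE 0.05) and ADE4, the enzyme of the first committed step (-1.55, SE 0.07), also fell. Smaller falls were those of ADE13 (-1.15), ADE8 (-0.89), ADE6 (-0.71) and ADE12, the first step from IMP to AMP (-0.42). ADE16, the isozyme of ADE17, differed by -0.22 (adjusted p = 0.0797 over all genes). The shift of the list against all other genes had an adjusted p of 1.9e-12 (camera, preset correlation), and an adjusted p of 0.163 with an estimated correlation. The number of fallen members was 5 without wild-type replicate 1, without PHO2 deletion replicate 1 or without PHO2 deletion replicate 2.

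One-carbon, glycine and serine genes fell together with the purine genes. Of 17 measured, 10 fell in the arrays labelled PHO2 deletion and 0 rose (12 fell and 1 rose when adjusted over the list alone). SER3, the isozyme of the first serine synthesis step, fell by 1.41 (SE 0.09, adjusted p = 0.0051). MTD1, the cytosolic methylenetetrahydrofolate dehydrogenase, fell by 1.12 (SE 0.08, adjusted p = 0.0067), and so did SER2 (-0.87) and SER1 (-0.61). SHM2, GCV1, GCV2, ADE3, SER33 and MIS1 fell as well, with differences from -0.52 to -0.43. The list median was -0.44 (camera adjusted p = 3.9e-07), with an adjusted p of 0.163 with an estimated correlation. Of the 7 measured histidine genes only HIS4, which encodes a multifunctional enzyme of the pathway, fell past the threshold over all genes (-1.55, SE 0.06, adjusted p = 5.4e-04). Adjusted over the list alone, 5 fell, with HIS1 at -0.34, HIS7 at -0.27 and HIS6 at -0.26, while the values of HIS2 and HIS3 were 0.04 and 0.06. The histidine list median was -0.27 (camera adjusted p = 0.0038), with an adjusted p of 0.438 with an estimated correlation. Without wild-type replicate 1 or PHO2 deletion replicate 1, 2 one-carbon members fell, and 1 fell without PHO2 deletion replicate 2; SER3 and HIS4 passed the test without any 1 array. SER1 did not pass without these 3 arrays (adjusted p from 0.0667 to 0.108), MTD1 not without wild-type replicate 1 (0.0574) or PHO2 deletion replicate 2 (0.0535), and SER2 not without PHO2 deletion replicate 1 (0.0723) or PHO2 deletion replicate 2 (0.0535).

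Genes of GMP synthesis and purine salvage moved in both directions. Of 15 measured, 3 rose and 1 fell in the arrays labelled PHO2 deletion, the same counts as when adjusted over the list alone. IMD2, an IMP dehydrogenase gene of the step from IMP towards GMP, rose by 1.47 (SE 0.08, adjusted p = 0.0023), on a probe set marked as shared between sequences. FCY21 rose by 3.02, as given above. APT1, adenine phosphoribosyltransferase, rose by 0.46 (SE 0.07, adjusted p = 0.0309), and HPT1, the phosphoribosyltransferase for hypoxanthine and guanine, fell to 40.5% of the wild-type level (SE 0.07 on the log2 scale, adjusted p = 0.0020). The other 11 did not pass the test, among them FCY2 (-0.24) and GUA1 (-0.21). The list as a whole was not shifted (camera adjusted p = 0.699): its median was -0.08, its mean 0.17 and the direction of its test downward. APT1 did not pass after a correction for coding length, nor without wild-type replicate 1 (adjusted p = 0.129), PHO2 deletion replicate 1 (0.216) or PHO2 deletion replicate 2 (0.154).

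Phosphate-responsive genes, known targets of Pho4 acting with Pho2 when phosphate is scarce, held no gene past the threshold over all genes. Of 18 measured, 0 rose and 0 fell past the threshold over all genes by limma, while 9 had an unadjusted p below 0.05, against 29.4% of all genes. Adjusted over the list alone, 2 rose and 4 fell. PHM8, a phosphatase gene, had the largest difference (2.46-fold higher, log2 SE 0.28, adjusted p = 0.0655), and the others with the smallest p were PHO89 (-0.28, adjusted p = 0.0647), VTC2 (-0.25, adjusted p = 0.0692) and VTC3 (-0.31, adjusted p = 0.0726). The acid phosphatase gene PHO5 differed by -0.22 (adjusted p = 0.0890) and the transporter gene PHO84 by -0.32 (adjusted p = 0.180). The list median was -0.05 and its mean 0.06, and the list was not shifted (camera adjusted p = 0.778). Alternatives called members in both directions: 5 fell and 0 rose with the arrays quantile normalized again, 3 fell and 2 rose with array weights, 3 fell and 1 rose without genes of 600 nt or less, 1 fell and 1 rose after the correction for coding length, and 1 fell and 0 rose with a trend in eBayes. The 7 genes of phosphate signalling and low-affinity transport held 0 risen and 0 fallen genes, also when adjusted over the list alone (median -0.09, camera adjusted p = 0.15). HO, where Pho2 acts with Swi5, differed by 0.10 (adjusted p = 0.284).

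General stress genes were higher in the arrays labelled PHO2 deletion. All 29 measured genes had positive differences, 11 rose and 0 fell (23 rose when adjusted over the list alone). The same 23 had an unadjusted p below 0.05 by limma, against 29.4% of all genes. YGP1 rose by 2.95, HSP12 by 1.69 (SE 0.20, adjusted p = 0.0211), the cell wall protein gene SPI1 from 9.44 to 10.44 (SE 0.14, adjusted p = 0.0288) and MSC1 by 0.50 (SE 0.06, adjusted p = 0.0188). SOL4, CTT1, DCS2, TFS1, GAD1, NTH1 and GRE3 rose by 0.34 to 1.06. The list median was 0.48 (camera adjusted p = 1.4e-11), with an adjusted p of 0.525 with an estimated correlation. Within wild-type, the stress list median of replicate 3 minus replicates 1 and 2 was -0.19, so these genes also varied without a genotype difference. Without wild-type replicate 3 the stress list median was 0.43. Genes of the tricarboxylic acid cycle and respiratory chain also rose more often than they fell. Of 43 measured, 10 rose and 1 fell (32 and 3 when adjusted over the list alone), with a median of 0.39 (camera adjusted p = 2.0e-09), and an adjusted p of 0.483 with an estimated correlation. SDH2 and SDH4, subunits of succinate dehydrogenase, rose by 0.64 (SE 0.06, adjusted p = 0.0145) and 0.60 (SE 0.06, adjusted p = 0.0152), and RIP1, the Rieske protein of the cytochrome bc1 complex, rose by 0.61 (SE 0.08, adjusted p = 0.0250). Aconitase, ACO1, fell by 0.39 (SE 0.06, adjusted p = 0.0312). Many respiratory genes are short, and short genes as a class were higher in the arrays labelled PHO2 deletion, as described below. SDH4 did not pass the test after the correction for coding length, and without genes of 600 nt or less the respiratory median was 0.18. The number of risen stress genes was 1 without wild-type replicate 1 or without either array labelled PHO2 deletion and 6 without wild-type replicate 3, and that of risen respiratory genes was 0 without the first 3 of these. Without each of those 3, HSP12, SPI1, MSC1, SDH2, SDH4, RIP1 and ACO1 missed the threshold (adjusted p from 0.0695 to 0.221), and ACO1 missed it also without wild-type replicate 2 (0.0554) or wild-type replicate 3 (0.0510).

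**Figure D2:**
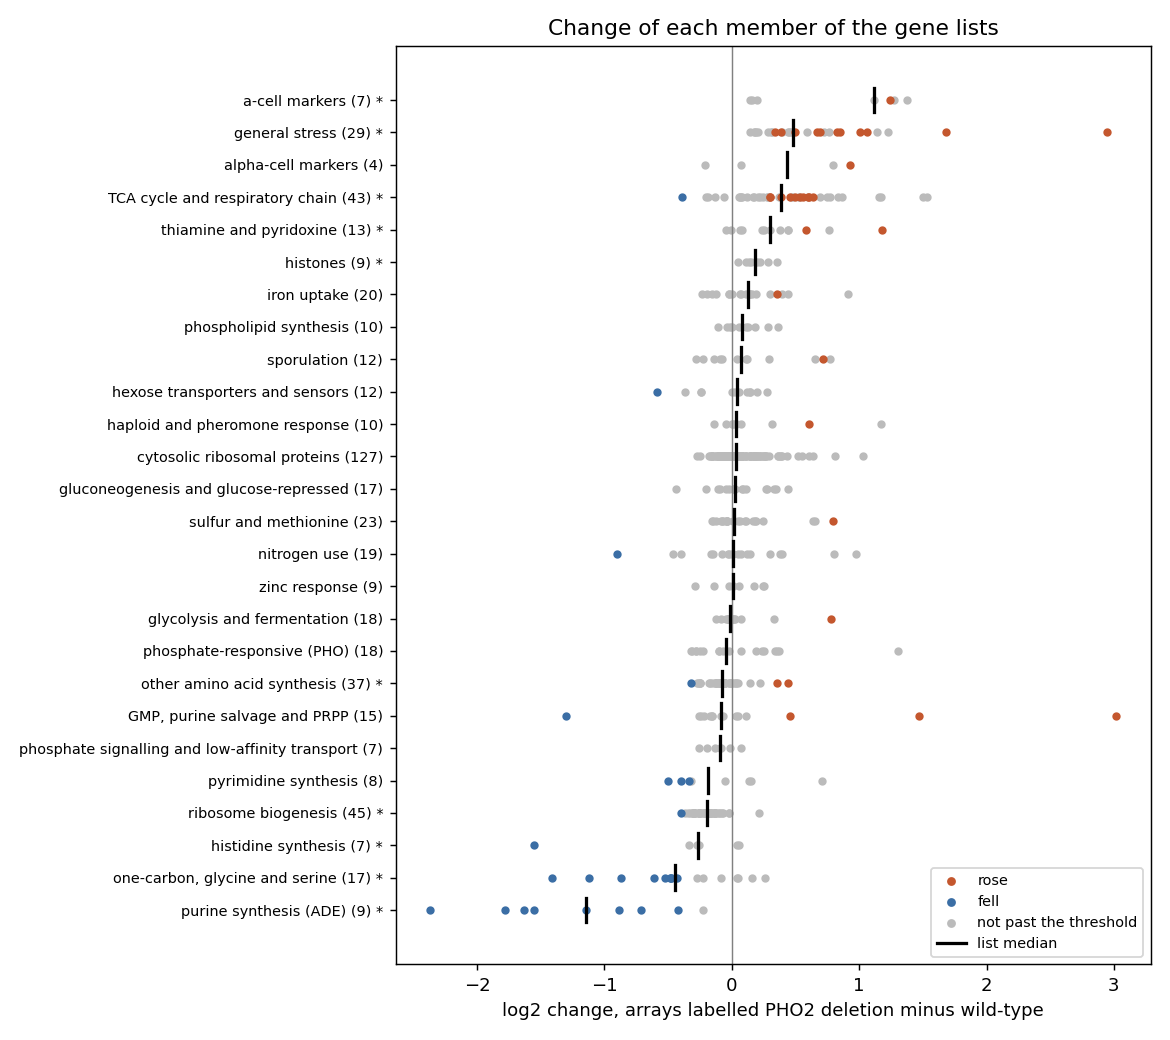
Log2 change in the arrays labelled PHO2 deletion against wild-type (x axis) of each measured member of the gene lists (y axis, number measured in brackets, ordered by median); points are genes, coloured by whether they rose, fell or did not pass the test, black bars are list medians, and an asterisk marks an adjusted camera p below the threshold with the preset correlation. Purine synthesis lies lowest, with a median of -1.15, and the a-cell markers highest, with a median of 1.11 from 7 genes of which 1 rose.

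Glycolysis and fermentation (18 genes) and the hexose transporters and sensors (12 genes) were not shifted as lists, with camera adjusted p of 0.988 and 0.745. TDH1, a glyceraldehyde-3-phosphate dehydrogenase isozyme, rose by 0.78 (SE 0.06, adjusted p = 0.0085) as the 1 called glycolytic gene, and HXT2, a glucose transporter, fell by 0.59 (SE 0.05, adjusted p = 0.0119) as the 1 called transporter gene, with the same counts when adjusted over each list alone. Median and mean differed in sign in both lists (-0.01 and 0.04 for glycolysis, 0.04 and -0.04 for the transporters), and both tests pointed downward. Gluconeogenesis and glucose-repressed genes (17 genes, median 0.03, camera adjusted p = 0.745) held 0 risen and 0 fallen genes. TDH1 and HXT2 did not pass the test without wild-type replicate 1 or either array labelled PHO2 deletion (adjusted p from 0.0654 to 0.14).

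Among 37 genes for other amino acids, ARG1 (0.44, adjusted p = 0.0312) and ARO3 (0.36, adjusted p = 0.0389) rose and ARG8 (-0.32, adjusted p = 0.0356) fell, and 3 rose and 5 fell when adjusted over the list alone. The median was -0.08 (camera adjusted p = 0.0149), with an adjusted p of 0.646 with an estimated correlation, and the shift was also lost when the arrays were quantile normalized again (adjusted p = 0.106), with every probe set tested (0.0509), after the correction for coding length (0.256) and without genes of 600 nt or less (0.108). Of 8 pyrimidine genes, URA4 (-0.50, adjusted p = 0.0152), URA1 (-0.40, adjusted p = 0.0318) and URA3 (-0.33, adjusted p = 0.0379) fell, with 1 risen and 4 fallen when adjusted over the list alone (median -0.19, camera adjusted p = 0.201). MUP1, the high-affinity methionine permease, was the 1 of 23 sulfur and methionine genes that rose (0.79, SE 0.10, adjusted p = 0.0241; list median 0.02, camera adjusted p = 0.632), also when adjusted over the list alone. PUT1, proline oxidase, was the 1 of 19 nitrogen-use genes that fell (-0.90, SE 0.06, adjusted p = 0.0060), with 2 risen and 3 fallen when adjusted over the list alone; that list had a median of 0.01, a mean of 0.05 and a test pointing downward (camera adjusted p = 0.948). Each of these 8 genes missed the threshold without wild-type replicate 1 or either array labelled PHO2 deletion (adjusted p from 0.0519 to 0.241). ARG1, ARG8, ARO3 and URA3 missed it without wild-type replicate 2 (0.0565 to 0.0614), and ARG8, ARO3, URA1 and URA3 without wild-type replicate 3 (0.0556 to 0.0599).

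Ribosomal protein genes showed no called change, while ribosome biogenesis genes were slightly lower as a list. Of 127 ribosomal protein genes 0 rose and 0 fell by limma, over all genes and when adjusted over the list alone. Their median was 0.03 (camera adjusted p = 0.745), which turned to -0.01 with array medians subtracted (adjusted p = 0.932), and the list was called as lower after a correction for coding length (median -0.06, adjusted p = 0.0112). Of 45 ribosome biogenesis genes, 44 had negative differences with a median of -0.19 (camera adjusted p = 3.3e-08), and an adjusted p of 0.646 with an estimated correlation. These genes also varied within wild-type, with a list median of 0.095 for replicate 3 minus replicates 1 and 2. UTP22, a component of the small subunit processome, was the 1 that fell (-0.40, SE 0.07, adjusted p = 0.0426), and 0 fell when adjusted over the list alone. UTP22 missed the threshold when any 1 array other than wild-type replicate 2 was left out, with adjusted p of 0.151 and 0.0591 without wild-type replicates 1 and 3 and of 0.241 and 0.185 without PHO2 deletion replicates 1 and 2.

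Mating-type markers were examined because they tell cell types apart. Among 7 a-cell markers, ASG7 rose by 1.24 (SE 0.14, adjusted p = 0.0192), and 5 rose when adjusted over the list alone. The short pheromone and agglutinin genes MFA1 (1.38, adjusted p = 0.0719) and AGA2 (1.28, adjusted p = 0.101) missed the threshold over all genes, and the longer STE2 differed by 0.20 (adjusted p = 0.123). The list median was 1.11 (camera adjusted p = 0.0019), with an adjusted p of 0.332 with an estimated correlation. It was 0.65 after the correction for coding length and 0.18 over the 4 members left without genes of 600 nt or less. With 1 array left out, the a-cell median ran from 0.72 (without wild-type replicate 3) to 1.29 (without wild-type replicate 2). Of 4 alpha-cell markers, STE3 rose by 0.93 (SE 0.14, adjusted p = 0.0312), from 7.58 to 8.50, and 2 rose when adjusted over the list alone (median 0.43, camera adjusted p = 0.298). STE2 was bright in wild-type (14.16) and in the arrays labelled PHO2 deletion (14.36), and MF(ALPHA)1 lay near the background bound of 6.44 in both (5.96 and 6.76). SAG1 (10.16 and 10.23) and MF(ALPHA)2 (8.28 and 8.07) were alike in both. These levels argue against opposite mating types in the groups. AGA1 was the 1 of 10 haploid and pheromone response genes that rose (0.61, adjusted p = 0.0439), with 3 when adjusted over the list alone (median 0.03, camera adjusted p = 0.310). NDT80 was the 1 of 12 sporulation genes that rose (0.72, adjusted p = 0.0472), with 2 risen and 1 fallen when adjusted over the list alone (median 0.08, camera adjusted p = 0.716). NDT80 missed the threshold with the arrays quantile normalized again (adjusted p = 0.0692) and with robust eBayes (0.0504), and AGA1 with array medians subtracted (0.0558). AGA1 missed the threshold when any 1 array was left out (adjusted p from 0.0540 to 0.194), ASG7 without wild-type replicate 1 or either array labelled PHO2 deletion (0.0852 to 0.153), STE3 without PHO2 deletion replicate 1 (0.114) or any 1 wild-type replicate 1, 2 or 3 (0.0562 to 0.124), and NDT80 without any 1 array other than wild-type replicate 3 (0.0593 to 0.240).

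Among the other lists, thiamine and pyridoxine genes were higher in the arrays labelled PHO2 deletion. Of 13 measured, 2 rose, THI13 of pyrimidine precursor synthesis (1.18, SE 0.14, adjusted p = 0.0211, on a shared probe set) and PET18 (0.59, SE 0.08, adjusted p = 0.0295), and 7 rose when adjusted over the list alone. The median was 0.30 (camera adjusted p = 0.0012), with an adjusted p of 0.438 with an estimated correlation, and 0.16 (adjusted p = 0.143) over the 6 members left without the genes of lowest signal. The 9 histone genes all had positive differences and 0 were called, over all genes or over the list alone. The histone median was 0.18 (camera adjusted p = 0.0178), with an adjusted p of 0.722 with an estimated correlation and of 0.184 without PHO2 deletion replicate 2. With 1 array left out, the histone median ran from 0.11 (without wild-type replicate 3) to 0.24 (without wild-type replicate 2). Histone genes are short, and after the correction for coding length their median turned to -0.13 (adjusted p = 0.0879). FIT1, a cell wall mannoprotein of iron uptake, was the 1 of 20 iron genes that rose (0.36, adjusted p = 0.0288), with 2 risen and 1 fallen when adjusted over the list alone (median 0.12, camera adjusted p = 0.161). The iron median ran from 0.05 (without PHO2 deletion replicate 1) to 0.16 (without PHO2 deletion replicate 2) with 1 array left out. The iron list was called as higher after the correction for coding length (adjusted p = 0.0429) and with every probe set tested (0.0495), and FIT1 missed the threshold with the arrays quantile normalized again (0.102). The 9 zinc genes (median 0.01, camera adjusted p = 0.745) and the 10 phospholipid genes (median 0.08, camera adjusted p = 0.298) held 0 called genes on either adjustment. THI13, PET18 and FIT1 missed the threshold without wild-type replicate 1 or either array labelled PHO2 deletion (adjusted p from 0.0752 to 0.210), and FIT1 also without wild-type replicate 2 (0.0532).

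Short genes stood apart between the groups and between single arrays. For the 537 genes with a coding length of 450 nt or less, the median difference was 0.44 in the arrays labelled PHO2 deletion, against -0.01 for the 4912 longer genes. Across genes, which are not independent replicates, length and change had a Spearman rho of -0.40. Short genes were also lower on wild-type replicate 3 than on the other wild-type arrays, relative to long genes (short minus long -0.37). Between the groups, short minus long was 0.45, and 0.30 without wild-type replicate 3. Ribosomal RNA probe sets moved with the groups as well: 14 of 17 had both arrays labelled PHO2 deletion below all wild-type arrays, with a median change of -1.06. No preparation batch is named for the samples. A difference in RNA preparation between the groups can therefore not be told apart from genotype, for these probe sets, the short genes or the called genes. The signal at the 3' end of the ACT1 control transcript exceeded that at its 5' end by 0.19 to 0.22 on the wild-type arrays and by 0.24 and 0.23 on the arrays labelled PHO2 deletion. For SPT15 these values overlapped (0.83 to 0.93 against 0.86 and 0.91), and for WBP1 they were 0.66 to 0.72 against 0.72 and 0.77. After a correction for coding length the respiratory list had a median of 0.21 and the a-cell list of 0.65, while that of the stress list was 0.51.

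**Figure D3:**
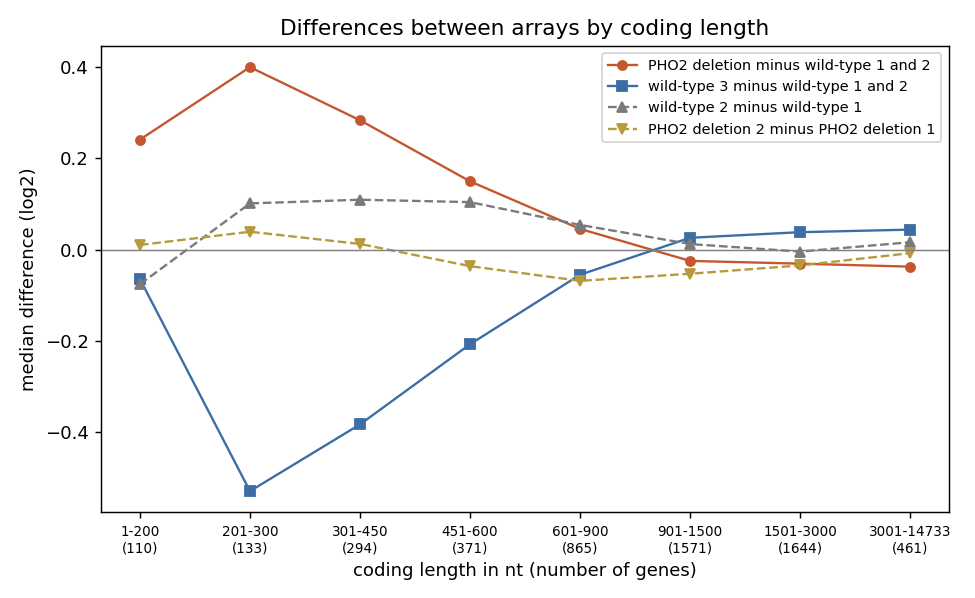
Median log2 difference between arrays (y axis) over genes grouped by coding length in nt (x axis, number of genes in brackets), for the arrays labelled PHO2 deletion against wild-type replicates 1 and 2, for wild-type replicate 3 against the same 2, and for the other pairs of replicates. In genes over 200 nt and up to 300 nt the median was 0.40 for the arrays labelled PHO2 deletion and -0.53 for wild-type replicate 3, while genes above 900 nt stayed within 0.05 of 0 in both.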

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

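Tests of the signal of other transcripts on the PHO2 probe set, of exchanged arrays, of short-RNA recovery and of the length trend in single lists were chosen or given their criterion only after the result was seen. Probe sets outside the gene annotation took no part in the comparison of genes, and 4 of them were higher in the arrays labelled PHO2 deletion than in wild-type at an adjusted p below 0.05 by limma. A reporter probe set lay below the background bound on all 3 wild-type arrays and far above it on both arrays labelled PHO2 deletion, whose mean was at least 243-fold higher than wild-type taken at the bound. Its fitted log2 difference of 9.95 rests on that background signal and is no measure of size. A pair of unnamed probe sets were higher by 1.92 (adjusted p = 0.0064) and 1.73 (adjusted p = 0.0352). A control probe set for the middle of TDH1 was higher by 1.31 (adjusted p = 0.0352), beside a rise of 0.78 for the TDH1 gene probe set.

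The PHO2 signal was not lower in the arrays labelled PHO2 deletion (10.07 and 10.84, against 10.38 to 10.72 in wild-type), although the reporter probe set and the purine genes separated the groups. An exchange of arrays between the groups would put at least 1 array with the other group in the purine list median, and 0 arrays lay there: the medians were 13.81 to 13.91 in wild-type and 12.06 and 12.08 in the others. Signal of other transcripts on the PHO2 probe set would leave both arrays labelled PHO2 deletion above background but below wild-type, and 1 of 2 lay below all wild-type arrays, which leaves this open. The arrays labelled PHO2 deletion differed by 0.77 in PHO2, more than 99.9% of 1339 genes of like brightness, whose median difference was 0.087. A deletion that left the probed part of PHO2 transcribed may also account for the signal and was not tested, since the positions of the deletion and the probes are not given in the sources used here.

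Short genes were higher in the arrays labelled PHO2 deletion (short minus long 0.45), and a difference in the recovery of short RNA between arrays is a candidate explanation. Within wild-type, where genotype is the same, replicate 3 deviated from the other replicates by -0.37 in short minus long genes, so a trend of nearly this size arises without a genotype difference; wild-type replicate 3 alone cannot be the whole source, since the contrast was 0.30 without it, against 0.05 between wild-type replicates 1 and 2 and 0.06 between the arrays labelled PHO2 deletion. The stress list has a median coding length of 1488 nt. Genes over 900 nt and up to 1500 nt had a median change of -0.03. The length correction could therefore hardly have lowered the stress median, 0.48 before and 0.51 after (camera adjusted p = 6.9e-12 after it, with the preset correlation). What argues against the length trend as the whole cause is the stress median of 0.46 over the 23 members left without genes of 600 nt or less. Other differences between arrays were not tested for this list. For the respiratory and a-cell lists the length correction left camera adjusted p of 4.7e-08 and 3.4e-04, but 55.2% and 58.0% of the medians. That is short of the 75% of the first criterion, which was loosened once results were seen and then set back. The medians of both lists were 0.18 without genes of 600 nt or less. With an estimated correlation the 3 lists had adjusted p of 0.525, 0.483 and 0.332 by camera before the correction. How far the trend may account for the respiratory and a-cell shifts stays open, as does a genotype effect on short transcripts, which was not tested.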

How the results depend on the processing

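The correction for coding length and the filter on genes of 600 nt or less were chosen after seeing the data; the other alternatives were fixed before. Under every alternative the PHO2 difference stayed short of the threshold. Without 1 array, 19 to 257 genes were called, 9 to 208 risen and 9 to 55 fallen (23 calls without wild-type replicate 1, 257 without wild-type replicate 2, 243 without wild-type replicate 3, 19 without PHO2 deletion replicate 1 and 26 without PHO2 deletion replicate 2). Against 275 calls (62.9% risen), a second quantile normalization gave 417 calls with 172 risen (41.2%) and 245 fallen, and 97 rose and 125 fell with the genes of lowest signal left out (4087 tested). Testing every probe set gave 40 calls (22 risen, 18 fallen), array weights 638 (372 risen, 266 fallen) and leaving out genes of 600 nt or less 489 (249 risen, 240 fallen). An adjusted p below 0.01 left 31 genes (17 risen, 14 fallen), a change of at least 1 log2 unit 55 (44 risen, 11 fallen), and an adjusted p below 0.10 gave 760 (418 risen, 342 fallen). Of 51 called genes picked by the naming rule, those of the list not reported here included, 14 passed the threshold under each alternative that tested them and 0 changed sign. With an estimated correlation the adjusted camera p was 0.163 for purine synthesis, 0.438 for histidine synthesis and 0.163 for the one-carbon list. For the same lists in that order, camera on ranks with the preset correlation gave 5.0e-06, 0.0148 and 2.1e-04. The fry test gave adjusted p of 1.7e-04, 0.0080 and 0.0024 for them. Of the 10 lists called by camera, fry, which tests against no change, left other amino acids (0.127), ribosome biogenesis (0.133) and histones (0.152) short of the threshold, and it called phosphate signalling (0.0227), pyrimidines (0.0143) and hexose transport (0.0242), which camera did not. After the length correction the histone list turned to the lower side (adjusted p = 0.0879). Fewer arrays, fewer genes or other thresholds account for some of these counts by construction; for the second normalization, the array weights and the histones the cause was not tested. Signal over background limits the 13 called genes with a group mean below the bound.

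With the replicate number as a replicate block, which leaves 1 residual degree of freedom, 35 genes were called (24 risen, 11 fallen), and the lists of histones and other amino acids had adjusted p of 0.0923 and 0.0531. The series' design text names no pairing, and the numbers were not taken to pair the samples. Deviations of same-numbered arrays correlated with r = -0.38 for number 1 and -0.0027 for number 2. With 2 arrays labelled PHO2 deletion, their deviations mirror each other, so each wild-type array has opposite values with them. Wild-type replicate 1 had 0.38 with PHO2 deletion replicate 2, and wild-type replicate 3 had 0.25 and -0.25 with replicates 1 and 2. These values cannot decide on pairing.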

Other observations

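The test of neighbouring genes was planned before its result was seen. PAU21, on a shared probe set of the seripauperin family, was bright on PHO2 deletion replicate 2 (13.69) and near background on PHO2 deletion replicate 1 (5.82) and on the wild-type arrays (4.91, 5.06 and 5.26), and was not called (adjusted p = 0.222). Of the 17 ribosomal RNA control probe sets, 3 for 25S rRNA passed the test among probe sets without annotation, at -1.85, -1.77 and -1.89, while those for other parts of 25S rRNA and for 5.8S rRNA had differences from -1.06 to 0.46. Those for 18S rRNA were lower on both arrays labelled PHO2 deletion than on all wild-type arrays, with differences from -1.47 to -0.63, and did not pass the test. An unnamed probe set was lower in the arrays labelled PHO2 deletion (log2 change -1.10, adjusted p = 0.0460).

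CEM1 fell by 1.32 in the arrays labelled PHO2 deletion, beside its convergent neighbour FCY22, which rose by 1.08 (adjusted p = 0.0087), and the FCY22 paralog FCY21, which rose by 3.02. A hypothesis is that genes converging on a risen gene tend to fall, as transcription interference could bring about. The 75 convergent neighbours of the 173 risen genes had a median change of 0.03, against -0.01 for 145 same-direction neighbours, and 3 convergent neighbours fell. Among 10000 random draws of as many genes the one-sided p for lower convergent neighbours was 0.861, so no such general tendency was detected, and the test says nothing of CEM1 alone.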
